A study of Mus musculus with 22 samples.

How the data were processed

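Single-cell RNA was measured with the 10x Chromium 3' assay in 22 libraries of mouse cells, which fall into 15 groups. Secondary mouse embryonic fibroblasts carry a doxycycline-inducible cassette of Oct4 (Pou5f1), Klf4, Sox2 and Myc. Per the labels, the cells were trypsinized on days 0, 2, 4, 6 and 8 of doxycycline and then, after withdrawal at day 8, from 2i on days 9, 10, 11, 12 and 16 and from serum medium on days 10, 12 and 16. The 2i medium is serum-free and holds an inhibitor of MEK, an inhibitor of GSK3 and LIF. An induced pluripotent stem cell (iPSC) line from the same fibroblasts was collected in each medium. The groups of days 2, 4, 6 and 8 and the 2i groups of days 9, 10 and 12 hold 2 libraries each, and the other 8 groups hold 1. Replicate numbers come from the sample titles, and what a replicate shares (a plate, a dish or a cell suspension) is not given in the sources used here. The p-values then measure only the spread between these samples, which may be technical. The labels of day 0 do not settle whether the cells were taken just before or just after doxycycline was added.

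The deposited matrices hold raw UMI counts per gene and barcode. Per the submitters' processing notes the reads were processed with STAR and Cell Ranger against mm10, and neither versions nor the annotation are named. Which barcodes count as cells had been settled before the matrices were deposited. A table of normalized values also exists and was not used here, because its unit was not established. Everything else was computed from the counts. The matrices held 68339 barcodes and 27998 genes. Barcodes with at least 1000 detected genes were kept, which gave 65792 cells and left out 2547 barcodes; 65781 cells, the number that the series states, have more than 1000. Gene symbols were those of the deposited files, and 65 symbols occur more than once, so genes were tracked by Ensembl identifier. Coordinates are from the GENCODE M21 annotation of GRCm38, the build also called mm10, and were found for all 371 genes named or listed.

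The kept cells hold 11653882 to 39717196 UMIs per library, in 1529 to 5139 cells per library, with a median of 3362 to 12782.5 UMIs per cell. Mitochondrial genes took 0.287% to 1.93% of the UMIs of a library, and ribosomal protein genes 16.1% to 32.6%. Intervals of levels (exact Poisson) and of shares (exact binomial, Clopper-Pearson) are at 95% and cover counting error only. A gene with 0 counts in a whole group was set to a floor of 3 counts over that group, and its fold is then given as a lower bound. Levels are given as CPM, the UMIs of a gene scaled by all UMIs of its library.

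Differences between groups were tested on the counts summed over the cells of each library with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood with robust fitting, TMM scaling and the default low-count filter. A single fit with 1 mean per group covered all 22 libraries and left 7 residual degrees of freedom. It tested 16659 genes at a common dispersion of 0.014. A lone library was assumed to vary like the replicated groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were day 2 with day 0, day 8 with day 2, serum day 10 with day 8, 2i day 9 with day 8, 2i day 12 with 2i day 9, 2i with serum as the mean over days 10, 12 and 16, the same medium difference on day 16 with that on day 10, and iPSC lines with day 16 as the mean over both media. Log2 fold changes are given with their standard error (SE). Single libraries of the 2 media on day 16, and the iPSC lines, were set side by side without a test.

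On counts simulated from the real means, with 200 changed genes, the test recovered 61 of the 100 genes changed 2-fold and 92 of the 100 changed 4-fold for day 2 against day 0, with 18 false calls among 16459 unchanged genes. For day 8 against day 2 it recovered 78 and 95, with 7 false calls. For 2i against serum it recovered 89 and 98, with 5 false calls, and for iPSC lines against day 16 it recovered 75 and 96, with 18 false calls. Each unchanged gene was given the same mean level in all libraries, with the fitted dispersion. These counts therefore do not test TMM scaling with many changed genes, nor the assumption on lone libraries. The same holds for the simulation within fibroblast-like cells below.

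Whether replicate numbers pair the libraries of different groups was checked by correlating replicate differences between the 7 replicated groups. Of the 21 correlations across genes, 1 was over 0.1 and 2 were under -0.1, with a range of -0.352 to 0.154 and a median of 0.00577. The numbers were therefore not used as pairs. Between the replicates of a group the genes varied more than counting allows, by a chi-square per degree of freedom of 5.23 on day 8, 6.04 on 2i day 9, 8.16 on day 6, 8.55 on 2i day 10, 42.5 on day 2, 50.02 on day 4 and 73.8 on 2i day 12.

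There were 25 gene lists: reprogramming factors, fibroblast, pluripotency, primed pluripotency, epithelial, mesenchymal regulators, trophoblast, neural, keratinocyte, muscle, endothelial, immune, S phase, G2/M phase, senescence and secreted factors, p53 targets, MEK/ERK feedback, Wnt/beta-catenin targets, cholesterol synthesis, glycolysis, interferon response, imprinted, DNA methylation, X inactivation and dissociation stress. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members called were also counted with p adjusted over the list alone. The genes named in each comparison were the 10 largest rises and 10 largest falls (5 and 5 in the single-step and interaction comparisons) among called genes with a mean of at least 20 CPM in the higher group, no overlap between the libraries of the 2 sides, and a symbol that is not a model, clone, pseudogene or mitochondrial name. To these were added up to 4 called members per list with the largest changes, and the 4 reprogramming factors whatever their result. Named genes outside this rule are marked as such. The results of 4 genes that the rule names are not reported here, and counts of named genes leave them out; counts over all genes and over lists keep them.

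Cells were scaled to 10000 UMIs, log-transformed and reduced to 2000 variable genes and 30 principal components, with all libraries together and no integration. A graph weighted by shared neighbours (15 per cell) was built with scikit-learn 1.9.0 and igraph 0.11.9. Cells were grouped on it with leidenalg 0.10.2 (Leiden, resolution 1, fixed seed). A cluster took the class of a marker list when at least 3 markers were at least 2-fold higher than in the other cells, with a pseudocount of 10 CPM, and detected in at least 10% of its cells. Of 35 clusters, 23 were named and 12 were not. A cluster with enough markers stayed unnamed when its 10 top genes held a marker of another class and none of its own, a rule added after the clusters were seen. Classes carry the suffix -like because the labels name no cell types. Shares of a class were compared between the media by an exact two-sided permutation of the medium labels within days, which has 18 arrangements and cannot give a p below 0.05556. Within fibroblast-like cells the edgeR test was repeated on 13 libraries with at least 50 such cells (13083 genes, 3 residual degrees of freedom); on simulated counts it recovered 84 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 18 false calls. For 7 genes the share of cells with a UMI was measured after each cell had been thinned to 2000 UMIs, leaving out cells with fewer (10 on 2i day 16 and 98 on serum day 16). Doublets were not called.

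The comparisons, tests, gene lists, marker lists, naming rule for genes and alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors, library size alone as scaling, no low-count filter, all barcodes, no 2% of cells with the most UMIs, 1000 cells per library, a minimum fold of 2, leaving out each replicate or day, fits over fewer libraries, a block for the replicate number, other clusterings and other thinning. Chosen after the data were seen were the alternatives with cells of more than 1000 genes and with variable genes that leave out those called between the media. The log2 changes shifted when library size replaced TMM, and the median shift over genes was 0.12 for day 2 against day 0, -0.45 for day 8 against day 2, 0.21 for serum day 10 against day 8, 0.28 for 2i day 12 against 2i day 9, -0.19 for 2i against serum, -0.44 for the medium difference on day 16 against day 10 and -0.13 for iPSC lines against day 16. All changes in the text are relative to TMM scaling. The called lists kept the sign of their median under library size scaling. Counts from the 3' end do not separate the cassette's transcripts from those of the endogenous genes, and reads shared with near-identical gene copies may lower the counts of genes such as Pou5f1, Gapdh, Pgk1, Eno1 and Ldha by an amount that was not measured.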

Results

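Mouse fibroblasts carrying inducible Oct4, Klf4, Sox2 and Myc were followed by single-cell RNA counts through 8 days of doxycycline and then, without it, 8 more days in 2i or in serum medium. The fibroblast gene Col1a1 fell within 2 days, the epithelial gene Epcam came by day 8, and on 2i day 12 both Col1a1 and the pluripotency gene Dppa5a had risen. The 2 media differed in Wnt targets, the only list called between them with an estimated correlation too (adjusted p = 0.0424), and this difference fell from day 10 to day 16. The 22 libraries hold 65792 cells. Levels are in CPM, the UMIs of a gene scaled by all UMIs of its library, and a change given as a rise or fall by an amount is on the log2 scale with its standard error (SE).

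**Figure D1:**
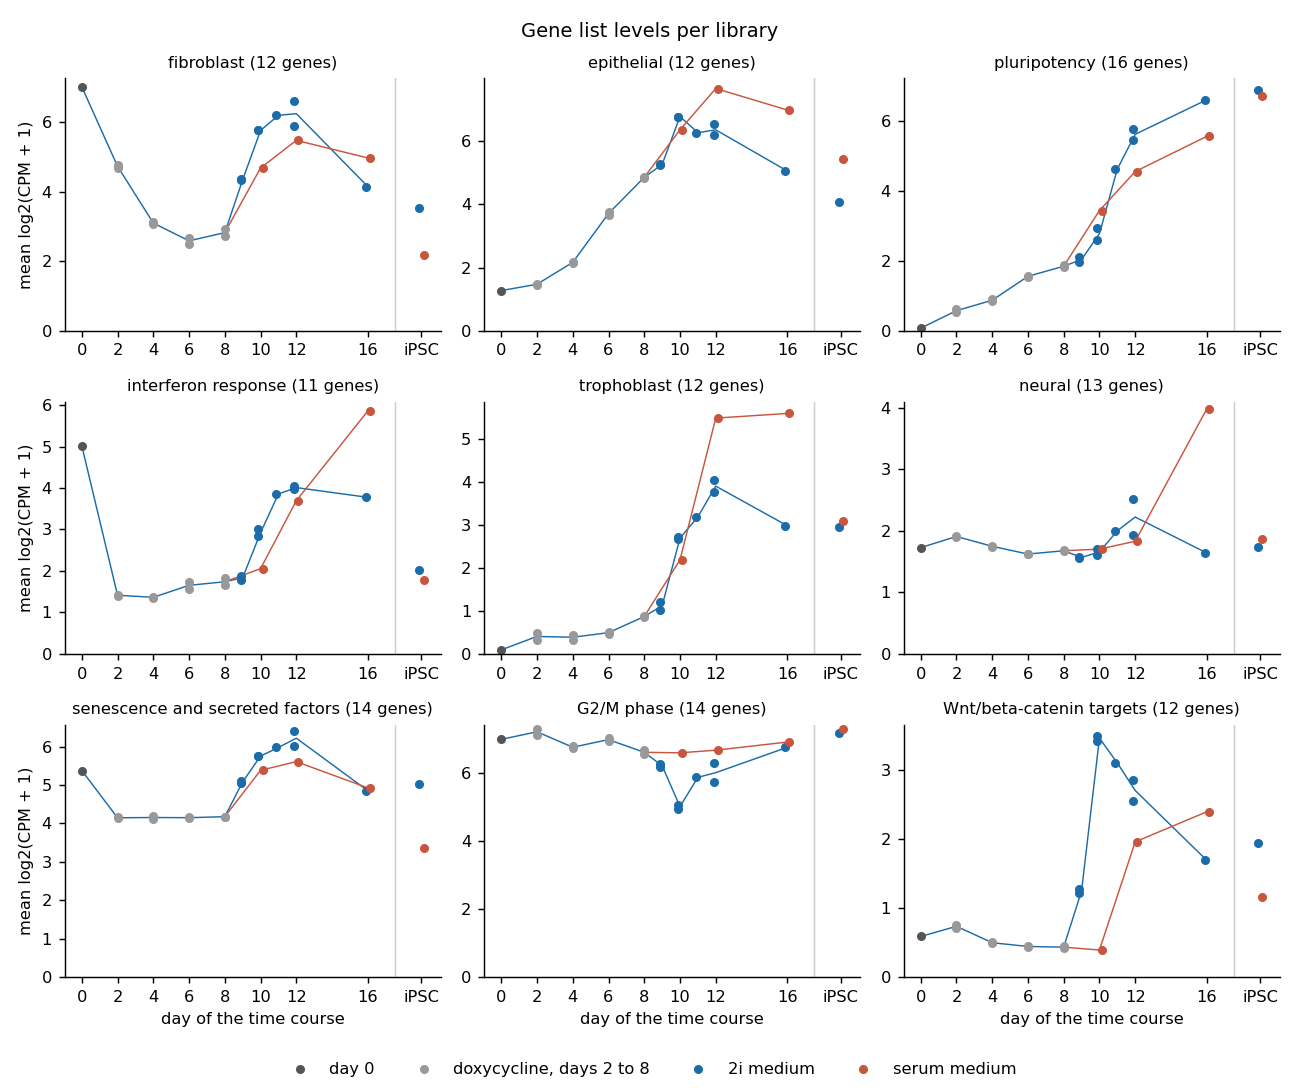
Mean log2(CPM + 1) over the members of 9 gene lists in each of the 22 libraries by day, with the iPSC lines at the right. Colours mark day 0, doxycycline, 2i and serum, and each point is 1 library.

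Between day 0 (1 library) and day 2 of doxycycline (2 libraries) the collagen gene Col1a1 fell from 2735 to 125 CPM, a log2 change of -4.58 (SE 0.28, adjusted p = 2.8e-08). Col3a1, Postn and the receptor gene Pdgfra fell by 4.43 (SE 0.38), 3.42 (SE 0.48) and 5.76 (SE 0.47). Snai1, which encodes a repressor of epithelial genes, fell 19.02-fold, from 74.1 to 4.30 CPM. Wisp2, a secreted CCN-family gene, fell from 282 to 0.177 CPM (log2 -10.62, SE 0.32), and the chemokine gene Cxcl12 fell from 443 to 2.48 CPM. Perp, a p53 target of cell junctions, rose 37.0-fold to 455 CPM. Of the 4 factors, Myc rose from 61.6 to 197 CPM (log2 1.55, SE 0.18) and Pou5f1 rose from 0 counts to 1.84 CPM, at least 16.96-fold; Klf4 (log2 0.54, SE 0.21) and Sox2 (log2 1.13, SE 0.63) were not called. A total of 6631 genes were called, 2846 up and 3785 down. The share of rises was 42.92% and became 50.84% when library size replaced TMM scaling.

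Interferon response genes had the lowest p of the 25 lists in this comparison. Isg15, a ubiquitin-like interferon target, was at 224.4 CPM on day 0 and 0.3315 CPM on day 2 (log2 -9.50, SE 0.39), and Ifit3 fell by 8.03 (SE 0.51). The day 2 libraries held 3 UMIs of Ifit1 (0.0601 CPM against 48.7 on day 0), 3 of Usp18 (0.0686 against 37.8 CPM), 1 of Rtp4 (0.0285 against 46.3 CPM) and 0 of Rsad2, at least a 35.86-fold fall. All 11 members of the list fell, with adjusted p = 1.01e-07 and p = 0.0474 with an estimated correlation, the only list of this comparison called in both ways.

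Among the largest rises were the neural transcription factor genes Neurog2, from 0 counts to 49.4 CPM, at least 455.2-fold, and Phox2a (log2 6.34, SE 0.29). Kpna7 went from 2 UMIs (0.0723 CPM) to 201 CPM, Crym from 2 UMIs (0.0723 CPM) to 67.9 CPM and Shisa8 from 3 UMIs (0.108 CPM) to 149 CPM. Aldh3a1, an aldehyde dehydrogenase gene, rose by 8.92 (SE 0.35) to 118 CPM, Urah by 6.56 (SE 0.30) to 122 CPM and Scg5 by 6.78 (SE 0.61). Crispld2, a secreted factor gene, went from 28.4 CPM to 3 UMIs (0.0857 CPM), and Foxs1 fell by 8.77 (SE 0.45). L1td1, a gene of pluripotent cells, rose from 0 counts to 19.04 CPM, at least 175.5-fold. Krt7, a simple-epithelium keratin, fell by 5.85 (SE 0.19) while Krt8 rose by 2.70 (SE 0.37), and the endothelial receptor gene Tek went from 1 UMI (0.0362 CPM) to 9.05 CPM.

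By list, 10 of 12 fibroblast genes fell (adjusted p = 1.32e-05, and 0.413 with an estimated correlation; other lists are given with the same 2 values in the same order). So did 7 of 10 mesenchymal regulators (0.00225, and 0.417). Of 10 imprinted genes 8 fell and 1 rose (0.00178, and 0.27), with H19 down by 4.13 (SE 0.17), Igf2 by 2.73 (SE 0.21) and Meg3 by 3.57 (SE 0.14). Of 12 p53 targets 9 rose (0.000572, and 0.417), among them Cdkn1a (log2 1.01, SE 0.25) and Mdm2 (log2 1.07, SE 0.27). S phase genes rose in 6 of 14 cases (0.00707, and 0.471), for example Mcm6 by 0.84 (SE 0.13). Secreted and senescence factors fell in 7 of 14 and rose in 2 (0.00739, and 0.417): Cxcl1 and Ccl2 fell by 4.92 (SE 0.23) and 4.00 (SE 0.23). Dissociation stress genes fell in 7 of 10 and rose in 1 (8 fell when adjusted over the list alone, 0.0136 and 0.417). The 4 factors as a list rose (2 called, 3 when adjusted over the list alone, 0.0228 and 0.417), and 3 of 16 pluripotency genes rose (0.0475, and 0.417). Day 0 had a single library, and its labels leave open whether doxycycline had just been added.

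From day 2 to day 8 (2 libraries each) Epcam, an epithelial adhesion gene, rose from 0.703 to 169 CPM (log2 8.34, SE 0.32). The cadherin gene Cdh1 went from 3 UMIs (0.0686 CPM) to 15.03 CPM, and the splicing factor gene Esrp1 and Ocln, a tight-junction gene, rose from 0 counts to 4.45 and 4.16 CPM, at least 63.02-fold and 58.84-fold. All 12 epithelial genes rose (adjusted p = 8.36e-09, and 0.289 with an estimated correlation). Nanog, a pluripotency factor gene, rose from 0.174 to 13.6 CPM (log2 6.76, SE 0.32), Utf1 by 6.27 (SE 0.42), and Nr0b1 from 0 counts to 26.0 CPM, at least 368.7-fold; 11 of 16 pluripotency genes rose (0.000628, and 0.402 with an estimated correlation). Lox, which encodes a collagen cross-linker, fell 80.7-fold, from 244 to 2.13 CPM. Fibroblast genes fell in 10 of 12 cases and rose in 1 (0.00258, and 0.598). Mesenchymal regulators fell in 7 of 10 and rose in 1 (0.0121, and 0.598; Twist2 -4.86, SE 0.42; Cdh2 -3.56, SE 0.26), and S phase genes fell in 10 of 14 (0.0323, and 0.667). A total of 8615 genes were called, 4247 up and 4368 down. The share of rises was 49.3% and became 28.27% with library size scaling, under which 296 called genes had the other sign.

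Other genes that rose were the male germline gene Dmrtc2 (log2 8.57, SE 0.24), to 204 CPM, and Apela (log2 8.66, SE 0.35), which encodes a secreted peptide. Ly6c1, a Ly6 surface antigen gene, and Ttyh1 each went from 3 UMIs (0.0601 CPM), to 33.6 and 22.6 CPM. Tac2 and Ckmt1 each went from 1 UMI on day 2, 0.0285 and 0.0200 CPM, to 59.6 and 29.8 CPM, and Lrmp from 3 UMIs (0.0686 CPM) to 43.2 CPM. Ly6g6c, with 4 UMIs on day 2, rose from 0.0972 to 158 CPM (log2 11.06, SE 0.28), and the stress keratin gene Krt17, also with 4 UMIs, rose from 0.0972 to 24.8 CPM (log2 8.39, SE 0.44). Neurog2, which had come up by day 2, fell by 5.86 (SE 0.33). The connexin gene Gjb2 fell by 6.47 (SE 0.34), S100a7a by 8.16 (SE 0.54) and the AP-1 gene Fosl1 fell 42.35-fold. Cdkn2a, the Ink4a/Arf locus of senescence, rose 4.39-fold to 648 CPM, and the p53 targets Bbc3 and Trp53inp1 rose 4.42-fold and 4.27-fold. The MEK/ERK feedback gene Dusp6 rose by 3.00 (SE 0.15), Bst2 of the interferon list by 3.34 (SE 0.14), the glucose transporter gene Slc2a1 by 2.21 (SE 0.11) and Meg3 by 2.82 (SE 0.13). Xist and Tsix, the only members of the X inactivation list, rose by 1.80 (SE 0.35) and 1.88 (SE 0.38), while the list itself was not called. Klf4 and Myc fell by 0.91 (SE 0.18) and 0.63 (SE 0.14), and Sox2 (log2 -0.39, SE 0.54) and Pou5f1 (log2 0.16, SE 0.39) were not called.

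Fibroblast and pluripotency genes were higher on serum day 10 than on day 8, though neither list was called with an estimated correlation (adjusted p = 0.139 for both). In the planned design this step was doxycycline withdrawal without a change of medium. Doxycycline and time changed together, so their effects were not separated. On serum day 10 (1 library) against day 8 (2 libraries), Spp1, which encodes the secreted matrix protein osteopontin, rose 89.8-fold, from 11.59 to 1191 CPM (log2 6.49, SE 0.58, adjusted p = 4.2e-05). Tdgf1, a Nodal co-receptor gene of pluripotent cells, rose from 0.953 to 49.2 CPM (log2 5.50, SE 0.45), and Dppa4 from 0 counts to 1.03 CPM, at least 11.71-fold. Col3a1, Lox and Col1a1 rose by 4.87 (SE 0.49), 3.82 (SE 0.26) and 2.91 (SE 0.28). Myc fell 3.10-fold to 34.5 CPM, while Klf4 (log2 0.29, SE 0.22) and Pou5f1 (log2 0.12, SE 0.46) were not called. Itga11 and Ly6d rose by 6.20 (SE 0.36) and 5.83 (SE 0.48), Krt18 by 3.44 (SE 0.20) and Krt17 by 2.94 (SE 0.24). Tac2, the gene of a neuropeptide, fell by 4.97 (SE 0.33), Ly6g6f by 5.05 (SE 0.35), Sptssb by 4.67 (SE 0.32), Acsbg1 by 4.30 (SE 0.22) and the Wnt effector gene Lef1 by 3.97 (SE 0.48). Of 3589 called genes 2132 rose and 1457 fell, and 2193 and 2181 were called without the first and the second day 8 replicate. The share of rises was 59.4% and became 80.82% with library size scaling.

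In that step 14 lists were called, and none was called with an estimated correlation. Rises came in 9 of 12 fibroblast genes (10 when adjusted over the list alone; adjusted p = 4.6e-07, and 0.139 with an estimated correlation), 13 of 16 pluripotency genes with 1 fall (3.63e-05, and 0.139) and 8 of 14 secreted and senescence factors (3.63e-05, and 0.139; Igfbp7 2.66, SE 0.15). They also came in 9 of 12 epithelial genes (7.42e-05, and 0.139) and 7 of 10 stress genes (0.000421, and 0.139; Junb 1.70, SE 0.14). Further rises were 7 of 10 mesenchymal regulators (0.000945, and 0.227; Tgfb1 2.38, SE 0.21), 7 of 10 imprinted genes with 1 fall (0.00725, and 0.139; Cdkn1c 1.80, SE 0.28) and 6 of 12 trophoblast genes (0.0127, and 0.28; Rhox6 4.32, SE 0.42). Smaller groups that rose were 3 of 8 muscle genes (4 when adjusted over the list alone, 0.013 and 0.139), 3 of 8 primed pluripotency genes (4 likewise, 0.0149 and 0.139; Lefty2 1.58, SE 0.30) and 5 of 9 keratinocyte genes with 1 fall (0.0383, and 0.139; Sfn 4.14, SE 0.45). Among the lists that fell was S phase (7 of 14, 0.00124 and 0.28; Rrm2 -1.14, SE 0.16). The others were glycolysis (3 of 11 with 1 rise, or 6 when adjusted over the list alone, 0.00914 and 0.232; Pgk1 -2.84, SE 0.56) and cholesterol synthesis (1 of 15, and 0 when adjusted over the list alone, 0.0155 and 0.273).

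The 2i medium holds a GSK3 inhibitor, which stabilizes beta-catenin, and a MEK inhibitor. Between day 8 and 2i day 9 (2 libraries each) the medium, doxycycline and time changed together, so their effects were not separated. In this step the Wnt target gene Axin2 rose from 0 counts to 5.29 CPM, at least 60.31-fold. Notum, which encodes a secreted Wnt inhibitor, rose from 0.105 CPM (4 UMIs) to 5.203 CPM (log2 5.37, SE 0.44), and Sp5 and Dkk1 rose from 0 counts, at least 20.17-fold and 7.60-fold. Dusp6, Etv4 and Etv5, which ERK signalling induces, fell by 2.33 (SE 0.15), 2.53 (SE 0.16) and 1.95 (SE 0.17), and Myc fell 3.92-fold to 24.6 CPM. Ndufa4l2, Slc16a3 and Slc2a1, genes of hypoxic and glycolytic metabolism, fell by 7.54 (SE 0.56), 6.06 (SE 0.25) and 1.35 (SE 0.10). Klf2, a factor gene of naive pluripotency, rose by 3.76 (SE 0.19), the glycoprotein gene Gpnmb by 4.36 (SE 0.24) and the chemokine gene Cxcl1 by 4.25 (SE 0.22), while Tac2 and Ly6g6d fell by 5.57 (SE 0.25) and 5.02 (SE 0.21). Klf4 (log2 0.03, SE 0.19), Sox2 (log2 0.11, SE 0.56) and Pou5f1 (log2 -0.23, SE 0.39) were not called.

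Of 12 Wnt targets 7 rose and 1 fell on 2i day 9 (adjusted p = 0.000189, and 0.0793 with an estimated correlation), and of 12 MEK/ERK feedback genes 6 fell and 1 rose (8 fell when adjusted over the list alone, 0.00134 and 0.564). Fibroblast genes rose in 9 of 12 cases (11 likewise, 1.33e-06 and 0.277), with Lum up from 1 UMI (0.0263 CPM) to 2.29 CPM and Col3a1 by 4.09 (SE 0.46). Rises also came in 8 of 14 senescence and secreted factors (10 likewise, 0.000181 and 0.337) and 6 of 10 mesenchymal regulators (0.0013, and 0.466). Glycolysis genes fell in 6 of 11 (7 likewise, 0.000189 and 0.277), G2/M genes in 7 of 14 (9 likewise, 0.00134 and 0.821; Cdc20 -0.94, SE 0.14) and S phase genes in 6 of 14 with 1 rise (7 likewise, 0.0266 and 0.821). Fgf4 and Nr0b1, pluripotency genes that had risen by day 8, fell by 1.12 (SE 0.19) and 1.26 (SE 0.21), and Lefty2 fell by 3.31 (SE 0.49). Of 4475 called genes 2338 rose and 2137 fell. The number was 2477 and 2733 without the first and the second day 8 replicate, and 2476 and 2816 without the first and the second 2i day 9 replicate.

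By 2i day 12 (2 libraries) most genes of the pluripotency list were higher than on 2i day 9. Dppa5a, which encodes an RNA-binding protein of embryonic stem cells, rose from 0.412 CPM on 2i day 9 to 1682 and 2718 CPM in the 2 replicates (log2 12.07, SE 0.64, adjusted p = 6.5e-08). Dppa3 and Dppa2 rose by 9.12 (SE 0.50) and 7.80 (SE 0.43), and Dppa4 from 3 UMIs (0.0536 CPM) to 24.6 CPM. Sox2 rose from 0.649 to 34.3 CPM (log2 5.42, SE 0.32) and Klf4 from 10.3 to 83.6 CPM (log2 2.74, SE 0.17), Myc fell by 1.70 (SE 0.15), and Pou5f1 was not called at 1.35 CPM (log2 -0.31, SE 0.37). Of 16 pluripotency genes 15 rose and 1 fell (1.45e-05, and 0.167 with an estimated correlation). Col1a1 rose again, to 804 CPM (log2 2.56, SE 0.24), with Lum up by 4.81 (SE 0.27) and Postn by 4.41 (SE 0.53). Rhox9, a placental homeobox gene, rose by 7.55 (SE 0.29), Plac1 by 6.95 (SE 0.31), and Gcm1 from 1 UMI (0.0200 CPM) to 20.7 CPM. The imprinted genes Igf2, H19, Cdkn1c and Peg10 rose by 5.37 (SE 0.23), 4.82 (SE 0.16), 4.65 (SE 0.25) and 3.69 (SE 0.16), though their list was not called.

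Interferon genes were higher on 2i day 12 than on 2i day 9, with 9 of 11 members up (10 when adjusted over the list alone; adjusted p = 0.000596, and 0.167 with an estimated correlation), among them Usp18 (log2 5.53, SE 0.38), Ifit1 (log2 5.00, SE 0.57) and Oasl2 (log2 4.97, SE 0.43). Their sum over the list was 430.3 and 402.1 CPM in the day 8 replicates, 271.4 and 297.4 CPM on 2i day 9 and 485.2 and 498.7 CPM on 2i day 12. Rises were called in 10 of 12 fibroblast genes (0.00209, and 0.494) and 8 of 12 trophoblast genes with 1 fall (0.0029, and 0.428). They were also called in 8 of 12 Wnt targets (0.0275, and 0.202; Cdx1 6.28, SE 0.39; Dkk1 5.35, SE 0.32) and 4 of 8 muscle genes (5 when adjusted over the list alone, 0.0407 and 0.333; Mylpf 5.16, SE 0.38). Mylpf was also among the 10 top genes of pluripotent-like clusters, so its rise need not come from muscle cells. G2/M genes fell in 5 of 14 (0.0105, and 0.735; Mki67 -1.88, SE 0.21). Krt18 rose from 63.85 to 1264 CPM and Krt7 by 4.50 (SE 0.14), Slc2a1 rose 10.2-fold, and the intermediate filament gene Vim fell from 3916 to 1615 CPM. Car4, a carbonic anhydrase gene, rose by 11.33 (SE 0.60), Gjb2 by 10.22 (SE 0.29), and Bhmt from 0 counts to 28.7 CPM, at least 524.0-fold. Dmrtc2, Lrmp, Pllp and Bcl11a fell by 7.13 (SE 0.22), 6.47 (SE 0.22), 6.09 (SE 0.17) and 4.04 (SE 0.15). A total of 7792 genes were called, 4519 up and 3273 down, and the share of rises was 58.0% or 78.93% with library size scaling. The 2 replicates of 2i day 12 differed in the share of fibroblast-like cells, 65.91% and 41.44%.

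Between the media, as a mean over days 10, 12 and 16 (5 libraries in 2i, 3 in serum), Wnt targets stood out in 2i. Notum was at 37.5 CPM in 2i and 3.06 CPM in serum (log2 3.82, SE 0.18, adjusted p = 1.7e-09), and Cdx1, an intestinal homeobox gene, at 17.4 and 2.09 CPM (log2 5.70, SE 0.29). The log2 values are means over days, so they can differ from the ratio of mean levels, as for Cdx1 with 0 counts on serum day 10. Saa3, the acute-phase serum amyloid gene, was at 382 and 10.9 CPM (log2 5.81, SE 0.72). Dusp6 was 4.79-fold lower in 2i (log2 -2.26, SE 0.11), and Myc, at 5.14 and 26.6 CPM, 6.14-fold lower. Dppa3 and Dppa5a were higher in 2i by 2.52 (SE 0.27) and 2.26 (SE 0.30), Klf4 by 1.26 (SE 0.13) and Sox2 by 1.02 (SE 0.18), and Pou5f1 was not called (log2 0.58, SE 0.34). Krt19, a simple-epithelium keratin, was lower by 3.18 (SE 0.12), Krt17 by 3.45 (SE 0.18), and Trh, the gene of thyrotropin-releasing hormone, by 3.24 (SE 0.24).

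**Figure D2:**
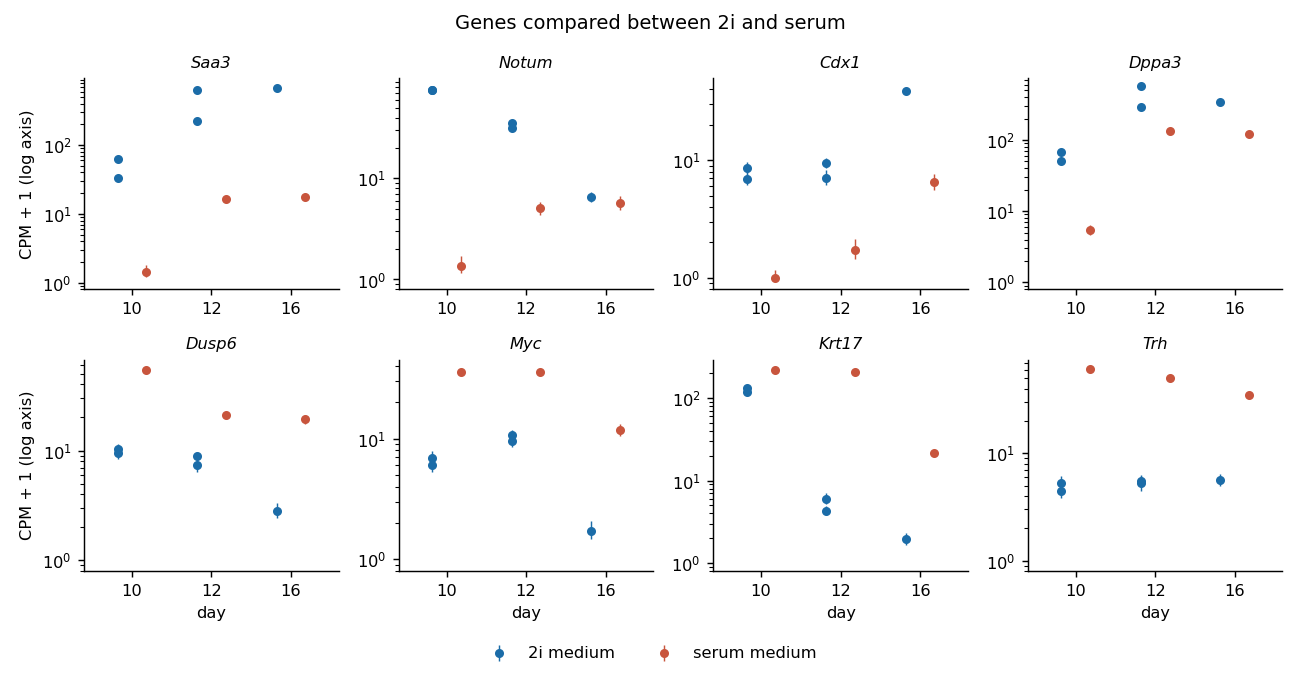
Levels of 8 genes in each library on days 10, 12 and 16 in 2i and in serum, as CPM + 1 on a log axis. Error bars are exact 95% Poisson intervals of the counts.

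Higher in 2i were also the phospholipase gene Pla1a (log2 3.87, SE 0.21) and Gpnmb (log2 3.46, SE 0.15). Spic (log2 3.74, SE 0.23), a macrophage factor gene that was among the top genes of pluripotent-like clusters here, was higher too. So were the fatty acid carrier gene Fabp3 (log2 3.12, SE 0.19), Npl (log2 2.73, SE 0.14), Calcoco2 (log2 2.70, SE 0.28), Lum (log2 3.13, SE 0.23, but 13.9 CPM in 2i and 44.65 CPM in serum on day 16) and Dcn (log2 1.95, SE 0.18). Lower in 2i were Upk3bl (log2 -4.44, SE 0.19), the transglutaminase gene Tgm1 (log2 -3.60, SE 0.14), Il1rn (log2 -3.38, SE 0.25), S100a14 (log2 -3.20, SE 0.14) and S100a4 (log2 -3.12, SE 0.16). The same held for Plet1 (log2 -3.04, SE 0.11), Elf5 (log2 -2.64, SE 0.18), Esam (log2 -3.94, SE 0.24) and Thy1 (log2 -1.38, SE 0.10). Serpinb9e was lower by 3.75 (SE 0.33).

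The Wnt list was the only list called with both correlations between the media: 10 of 12 targets were higher in 2i, with adjusted p = 6.84e-05 and 0.0424 with an estimated correlation. Sp5 was among them (log2 2.90, SE 0.40) but had the other sign without day 10 (log2 -0.56), as had Rnf43 (log2 2.98, SE 0.67, and -0.15 without day 10). Other lists higher in 2i were cholesterol synthesis (11 of 15, or 13 adjusted over the list alone, 6.84e-05 and 0.109 with an estimated correlation; Insig1 1.18, SE 0.14; Cyp51 1.02, SE 0.10) and pluripotency (11 up and 2 down of 16, 0.0173 and 0.315). Of higher p were fibroblast (7 up and 1 down of 12, 0.0312 and 0.458) and p53 targets (5 up and 1 down of 12, 0.0399 and 0.472; Cdkn1a at 1421 and 726.9 CPM).

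Lower in 2i were G2/M phase (13 of 14, or 14 adjusted over the list alone; adjusted p = 9.83e-05, and 0.458 with an estimated correlation; Mki67 -1.51, SE 0.14) and imprinted (9 of 10, 0.000207 and 0.0746; H19 -1.52, SE 0.10; Mirg -1.64, SE 0.14). The same direction held for keratinocyte (8 of 9, or 9 likewise, 0.000431 and 0.062; Krt14 -3.52, SE 0.48, but 25.00 CPM in 2i and 12.18 CPM in serum on day 10) and MEK/ERK feedback (7 of 12, and 1 up likewise, 0.000732 and 0.315; Etv4 -1.84, SE 0.12 and Egr1 -1.48, SE 0.13). So were dissociation stress (7 of 10, 0.000732 and 0.169; Fosb -1.68, SE 0.19) and epithelial (9 down and 1 up of 12, or 10 down likewise, 0.00186 and 0.315; Dsp -1.54, SE 0.12). The last were endothelial (3 down and 1 up of 7, 0.0141 and 0.184) and S phase (6 of 14, 0.0248 and 0.458; Rrm1 -0.45, SE 0.07). All 4 called genes among 8 of primed pluripotency were lower (0.00042, and 0.0733): Pou3f1 (log2 -1.57, SE 0.20), Fgf5 (0.0429 and 2.51 CPM), Lefty2 (log2 -1.29, SE 0.19, but 0.84 without day 10) and Dnmt3b (log2 -0.68, SE 0.13, but 0.36 without day 12).

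The remaining lists were not called between the media. Trophoblast had 2 genes up and 7 down of 12 (adjusted p = 0.0527), and neural 4 down of 13 (0.0693; Fabp7 -2.49, SE 0.20). Next came senescence and secreted factors (7 up and 1 down of 14, 0.0693; Cxcl1 2.19, SE 0.13) and glycolysis (3 down of 11, 0.161; Ldha -0.71, SE 0.10). DNA methylation (1 up and 3 down of 8, 0.311; Dnmt1 -0.76, SE 0.10), immune (1 up of 5, 0.343) and muscle genes (1 up and 4 down of 8, 0.356; Actc1 at 0.822 and 13.1 CPM) followed. The highest p were those of mesenchymal regulators (2 up and 4 down of 10, 0.516), reprogramming factors (2 up and 1 down of 4, 0.571), X inactivation (1 up of 2, 0.744) and interferon response (1 down of 11, 0.951).

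In all, 5249 genes were called between the media, 2418 higher and 2831 lower in 2i, and the share of higher genes was 46.07% or 22.14% with library size scaling. A fit of the 8 libraries alone, with day and medium as additive terms, called 265 genes (142 higher, 123 lower, 262 shared), and there a medium difference that varies between days counts as spread. Of 40 splits of these libraries into sets of 5 and 3, the real one included, only the real one called as many genes. The next, with the day 16 labels exchanged, called 5004. All other splits put 2i and serum libraries of some day under the same label, which adds the medium difference to the spread. A lower count was thus likely beforehand, and the rank does not decide whether the media differ. The fit called 5091, 5730 and 5128 genes without days 10, 12 and 16, and 13, 4 and 31 called genes then had the other sign.

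The medium difference itself changed between day 10 (2 libraries in 2i, 1 in serum) and day 16 (1 each). On day 10 Nkd1, a feedback inhibitor of Wnt signalling, was at 65.4 CPM in 2i and 0.535 in serum, and Notum at 74.6 and 0.357; on day 16 Nkd1 was at 2.71 and 25.1 CPM, and Notum at 5.52 and 4.75. All 12 Wnt targets fell in this interaction (adjusted p = 8.49e-08, and 0.0108 with an estimated correlation), among them Nkd1 (log2 -9.69, SE 0.39). Sp5 was at 43.93 CPM in 2i and 0.0446 CPM (1 UMI) in serum on day 10, and at 3.382 and 11.81 CPM on day 16. Cell cycle genes moved toward 2i: all 14 G2/M genes (1.88e-07, and 0.241; Cenpf 2.58, SE 0.40) and 12 of 14 S phase genes (4.3e-06, and 0.241; Uhrf1 1.96, SE 0.28). The pluripotency genes Nr0b1, L1td1, Fgf4 and Utf1 rose in it by 6.57 (SE 0.44), 5.11 (SE 0.30), 4.47 (SE 0.35) and 3.90 (SE 0.39), as did Cth (log2 6.25, SE 0.24) and Klf4 (log2 1.61, SE 0.31). Pou5f1 rose by 4.40 (SE 0.78) on levels of at most 2.83 CPM in any group, and Sox2 (log2 -0.48, SE 0.48) and Myc (log2 -0.78, SE 0.36) were not called. Lum, Krt7, Krt19 and Cdh2 fell by 8.53 (SE 0.61), 5.98 (SE 0.24), 4.34 (SE 0.30) and 5.53 (SE 0.51).

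Pluripotency genes rose in 10 of 16 cases (11, with 1 fall, adjusted over the list alone; adjusted p = 0.000152, and 0.144 with an estimated correlation). The falls were imprinted (9 of 10, 1.47e-05 and 0.0627; Peg10 -6.42, SE 0.32; Cdkn1c -5.93, SE 0.45) and mesenchymal regulators (7 of 10, or 8 likewise, 0.00106 and 0.241). Keratinocyte (7 of 9, or 8 likewise, 0.00126 and 0.0627; Trp63 -5.50, SE 0.73), interferon (9 of 11, 0.0014 and 0.144; Usp18 -6.33, SE 0.67) and epithelial genes (7 of 12, 0.00191 and 0.241) fell too. Further falls were trophoblast (9 of 12 with 1 rise, 0.00393 and 0.241; Plac1 -5.93, SE 0.48) and neural (7 of 13 with 2 rises, 0.00783 and 0.241; Tubb3 -6.31, SE 0.74). The last were stress (7 of 10 with 1 rise, or 8 down likewise, 0.00805 and 0.241) and fibroblast genes (6 of 12, 0.043 and 0.543). A total of 5722 genes were called, 2558 up and 3164 down, and the share of rises was 44.7% or 21.08% with library size scaling. The 2 day 16 libraries and serum day 10 were single, so a fault of any 1 of them would enter all of these genes.

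Set side by side with 1 library each on day 16, 2i and serum had Saa3 at 671.6 CPM [663.2 to 680.0] and 16.69 CPM [15.04 to 18.46], and Dppa5a at 9205 and 2414 CPM. Gpx6 was at 44.69 and 1.465 CPM and Trpm1 at 52.83 and 2.308 CPM. Serum held the placental genes Tpbpa at 863.2 CPM (0.0541 in 2i, 2 UMIs), Prl7d1 at 710.9 (0.0812, 3 UMIs), Ctsj at 886.6 (0.108) and Prl4a1 at 179.2 (0 counts in 2i). It also held the basal keratin gene Krt15 at 199.6 CPM (0.0271 in 2i, 1 UMI), and H19, Isg15 and Dlk1 at 1108, 431.6 and 170.0 CPM, against 69.8, 58.11 and 1.407 CPM. In serum day 16 the placental transcripts also appeared outside trophoblast-like cells: Ctsj was at 5788 CPM in those 301 cells and 310.4 CPM in the other 3404, and Tpbpa at 6299 and 224.1 CPM, so part of these genes' presence elsewhere may be free RNA. The 2i iPSC line held 7.647% fibroblast-like cells and the serum line 1.295%. Of the 2i line, 203 cells were in a cluster led by Saa3 and Lcn2. The levels below are of whole lines, not of their pluripotent-like cells alone. Between the iPSC lines, 1 per medium, Mmp3 was at 116.7 CPM in 2i and 1.387 in serum, Lcn2 at 104.3 and 1.097, Adh1 at 31.37 and 0.0968 (3 UMIs), Pramel6 at 22.49 and 0.0645 (2 UMIs), and Cdkn1a at 589.8 and 196.8. Lefty1 was at 3.911 and 111.2 CPM, Aldoc at 2.775 and 101.8, Slc16a3 at 4.254 and 140.5, and Epcam at 25.58 and 220.4.

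The iPSC lines (1 per medium) were compared with day 16 cells (1 per medium), and no list was called with an estimated correlation. Igf2, the imprinted growth factor gene, was at 0.694 CPM in the lines and 72.3 CPM on day 16 (log2 -6.01, SE 0.26, adjusted p = 1.7e-09), and Cdkn1c, an imprinted cell cycle inhibitor gene, fell by 5.53 (SE 0.27). Isg15, Usp18 and Ifit1 fell by 5.38 (SE 0.27), 6.29 (SE 0.33) and 6.16 (SE 0.56). Lefty2, Dnmt3b and Dnmt3l, the first a Nodal antagonist gene and the others genes of DNA methylation, rose by 2.22 (SE 0.15), 2.15 (SE 0.17) and 1.86 (SE 0.16). Rasgrp2 rose by 3.09 (SE 0.15), Gpx2 by 2.84 (SE 0.38), Krt42 by 2.56 (SE 0.27), Khdc3 by 1.89 (SE 0.16) and Etv4 by 1.77 (SE 0.16). Among the factors Sox2, Klf4 and Pou5f1 rose by 1.03 (SE 0.21), 0.82 (SE 0.16) and 1.47 (SE 0.38), and Myc was not called (log2 -0.28, SE 0.22). Xist fell by 2.64 (SE 0.37), Krt18 by 2.95 (SE 0.18), Krt8 by 2.52 (SE 0.14), and Cdkn2b by 2.07 (SE 0.14). Lum fell as well (log2 -5.72, SE 0.39), and so did Cdkn2a (log2 -1.98, SE 0.17), which was not called in 2i alone (log2 -0.63). Ceacam9 went from 53.4 CPM to 0.0161 CPM, 1 UMI in both lines together, and the placental genes Ctsj and Prl7d1 fell by 6.70 (SE 1.19) and 5.92 (SE 0.99) on the levels of the serum library.

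Called lists that rose in the lines were S phase (14 of 14; adjusted p = 8.32e-09, and 0.145 with an estimated correlation; Mcm4 1.12, SE 0.11) and G2/M phase (10 of 14, 0.000244 and 0.427). Others were glycolysis (7 of 11, 0.000376 and 0.145; Hk2 1.51, SE 0.33), pluripotency (13 of 16, 0.000415 and 0.145; L1td1 1.74, SE 0.16) and DNA methylation (6 up and 1 down of 8, 0.0111 and 0.145). Those that fell were interferon (11 of 11, 7.42e-07 and 0.0741), imprinted (8 of 10, or 9 adjusted over the list alone, 2.76e-05 and 0.0925; Grb10 -2.85, SE 0.19) and fibroblast (12 of 12, 2.76e-05 and 0.15). So did epithelial genes (10 of 12, 0.000415 and 0.177) and mesenchymal regulators (8 of 10, or 9 likewise, 0.00114 and 0.213; Tgfbr2 -1.66, SE 0.22). The others were endothelial (2 of 7, 0.00562 and 0.145), neural (6 down and 1 up of 13, 0.0248 and 0.308; Fabp7 -4.78, SE 0.35) and keratinocyte (3 of 9, 0.0401 and 0.148; Trp63 -3.30, SE 0.59). A total of 6083 genes were called, 2432 up and 3651 down, with 39.98% rises or 25.7% under library size scaling. The numbers were 3018 in 2i alone and 7381 in serum alone. Of these, 1985 and 4743 were also called in the mean over both media with the same sign, and 50 and 32 with the other sign. Of 96 called named genes, 41 stayed the same in 2i alone, 46 lost their call and 9 had the other sign. In serum alone these numbers were 89, 6 and 1. On day 16 the 2i library held 85.78% pluripotent-like cells and the serum library 0.9447%, so the lines were compared with different mixtures of cells.

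**Figure D3:**
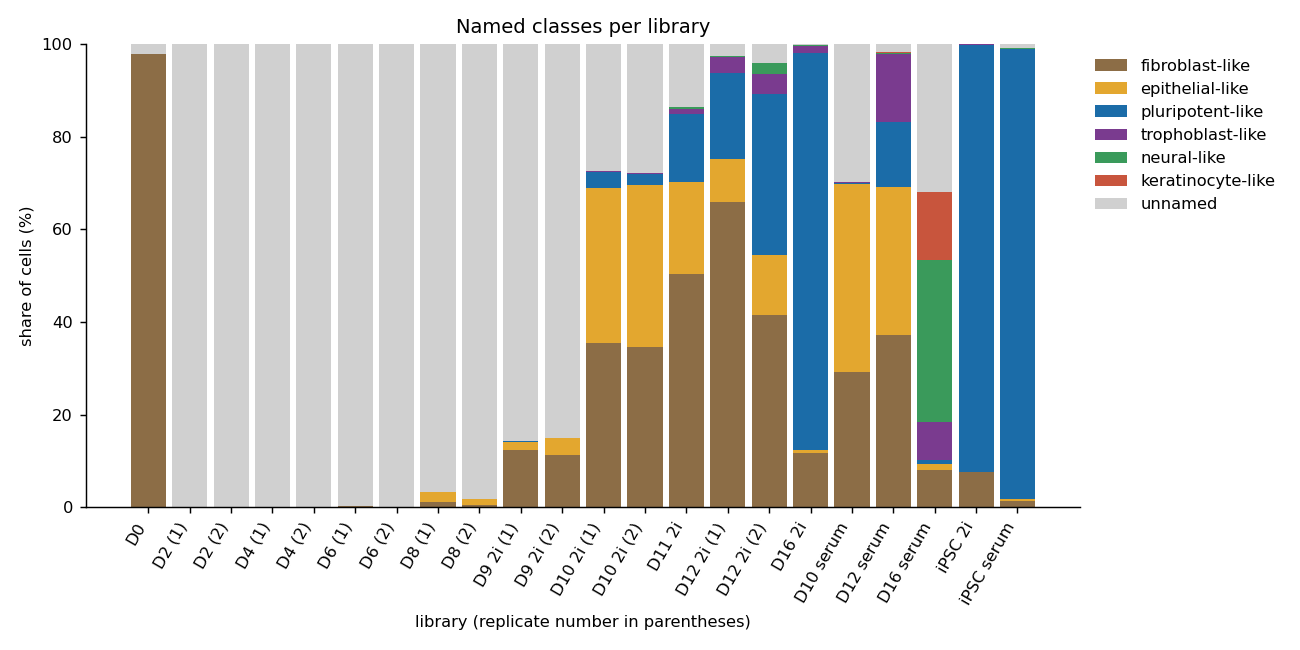
Share of the cells of each library in each class, stacked to 100%, with cells of unnamed clusters shown apart. The epithelial-like class is less sure, since a cluster in it had 2 markers of another class and 1 of its own among its 10 top genes. Part of the fibroblast-like class is less sure too, since 2 of its clusters had only 4 and 5 markers at least 2-fold higher.

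Clustering put 97.83% [97.34 to 98.26] of day 0 cells in fibroblast-like clusters and 0.025% to 1.03% on days 2 to 8, when 96.7% to 99.97% of cells were in clusters without a class. Of day 0 cells 92.88% were in 1 cluster that took 97.92% of its cells from that library. The fibroblast-like cells of later libraries thus lay mostly in other clusters. After withdrawal, fibroblast-like cells were 12.25% and 11.22% in the replicates of 2i day 9, 35.41% and 34.56% on day 10 and 50.29% on day 11. They were 65.91% [64.59 to 67.2] and 41.44% [39.35 to 43.55] on day 12 and 11.78% on day 16, and in serum 29.12%, 37.2% and 8.124% on days 10, 12 and 16. In the 2 replicates of 2i day 12, 28.37% and 18.05% of cells lay in a fibroblast-like cluster led by Saa3 and Lcn2. Only 4 fibroblast markers were at least 2-fold higher in that cluster. Another 6.908% and 5.754% lay in a cluster with 5 such markers, so part of this class is less sure. Pluripotent-like cells were 18.58% [17.53 to 19.67] and 34.85% [32.84 to 36.9] on 2i day 12, 85.78% [84.73 to 86.79] on 2i day 16, 14.16% on serum day 12, 0.9447% [0.6589 to 1.311] on serum day 16, and 92.22% and 97.12% in the 2i and serum iPSC lines. On serum day 16 a further 31.66% [30.16 to 33.19] of cells were in an unnamed cluster in which 12 pluripotency markers were at least 2-fold higher than elsewhere, and which was led by Stra8, Dazl and Rhox1, with the placental genes Prl7d1, Ctsj and Prl4a1 among its 10 top genes. It stayed unnamed by the rule added after the clusters were seen, because those 10 genes held Rhox9 of the trophoblast list and no pluripotency marker. The placental genes among them may reflect free RNA, as said of that library above. Counted as pluripotent-like, the cells of this cluster would raise the serum mean given below, and that difference was not tested. Serum day 16 also held 35.09% [33.55 to 36.65] neural-like, 14.6% [13.48 to 15.78] keratinocyte-like and 8.124% trophoblast-like cells, and serum day 12 14.54% [13.28 to 15.88] trophoblast-like cells, against 3.347% and 4.316% on 2i day 12. No cluster was named muscle-like, endothelial-like or immune-like, which does not exclude such cells within other clusters; the endothelial gene Cdh5 was at 25.96 CPM on serum day 16 and 0 counts on 2i day 16. Averaged over days 10, 12 and 16, fibroblast-like cells were 33.48% in 2i and 24.82% in serum (exact permutation p = 0.2222), and pluripotent-like cells 38.49% and 5.131% (exact permutation p = 0.2222), leaving out the unnamed cluster above. The fibroblast-like share of a library moved by up to 27.8 points with 50 components and 25.5 at resolution 2, far more than the counting intervals. At resolution 2 the pluripotent-like share of a library moved by up to 12.5 points, and the serum mean was 0.87% (exact permutation p = 0.05556). The fibroblast-like difference of 8.661 points became 0.9796 at resolution 0.5 and 0.8095 with 50 components, and turned to -2.545 at resolution 2 and -1.638 without the 2% of cells with the most UMIs. The differences by the same exact permutation were -5.789 points for trophoblast-like (p = 0.1111), -11.26 for neural-like (p = 0.7222) and -4.948 for keratinocyte-like cells (p = 0.1667), where the smallest possible p is 0.05556. At resolution 0.5 the keratinocyte-like difference was -15.66 points (exact permutation p = 0.05556) and the trophoblast-like one -2.47 (exact permutation p = 0.3889). Epithelial-like cells were 15.31% in 2i and 24.53% in serum, a difference of -9.226 points (exact permutation p = 0.05556). It was -3.6 points at resolution 0.5 (exact permutation p = 0.3333). A cluster of this class had more markers of another class than of its own among its 10 top genes, so this difference is less sure.

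Within fibroblast-like cells the media also differed, with 5 libraries in 2i and 3 in serum. Each serum day held 1 library. The spread behind these p-values, with 3 residual degrees of freedom, thus came from replicated 2i groups alone. Ptgds, the gene of a prostaglandin synthase, was at 52.6 CPM in 2i and 0.0453 CPM in serum (adjusted p = 0.01075), and the matrix genes Mfap4 and Dcn were higher in 2i by 3.15 (SE 0.15) and 2.93 (SE 0.11). Lum was higher by 3.15 (SE 0.13) as a mean over days on the log2 scale, but its mean levels were close, at 169.4 and 135.5 CPM. The contractile gene Cnn1 was at 13.7 and 200.9 CPM (log2 -3.90, SE 0.17), Il1rn, an interleukin 1 antagonist gene, at 11.0 and 174.7 CPM (log2 -3.81, SE 0.13), and Slc16a11 at 3.07 and 68.04 CPM (log2 -4.39, SE 0.17). Trib3, a gene of the amino acid stress response, was higher in 2i by 3.65 (SE 0.25), Steap4 by 3.08 (SE 0.28), Serpina3n by 2.97 (SE 0.29), Cxcl1 by 2.33 (SE 0.19) and Ccl2 by 2.14 (SE 0.27). Plac8, Krt19, Thy1 and Myc were lower by 6.07 (SE 0.46), 2.61 (SE 0.28), 1.82 (SE 0.24) and 1.08 (SE 0.19). Called were 2317 genes, 1168 higher and 1149 lower. The number was 3500 and 3979 without the first and the second 2i day 12 replicate. Of 4628 shared genes called in whole libraries, 1316 were called here in the same direction and 76 in the opposite one.

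In these cells 12 of 14 G2/M genes were lower in 2i (14 adjusted over the list alone; adjusted p = 1.3e-06, and 0.309 with an estimated correlation; Tpx2 -1.78, SE 0.20), as were keratinocyte genes (3 of 7, 0.00157 and 0.309). So were imprinted genes (5 of 10, 0.00513 and 0.309; H19 -1.75, SE 0.09; Igf2 -1.49, SE 0.14), epithelial genes (2 of 10, or 7 likewise, 0.0127 and 0.522) and MEK/ERK feedback genes (5 down and 1 up of 12, 0.0217 and 0.309; Dusp6 -1.09, SE 0.18). Higher were p53 targets (6 of 12, or 8 likewise, 0.00513 and 0.496; Sesn2 0.89, SE 0.12; Cdkn1a 0.55, SE 0.10) and Wnt targets (2 of 8, 0.00633 and 0.309; Nkd1 2.21, SE 0.18). So were fibroblast genes (5 up and 1 down of 12, 0.0315 and 0.399), glycolysis (5 up and 1 down of 11, 0.0315 and 0.309) and pluripotency genes (4 up and 1 down of 16, 0.0474 and 0.547). For the keratinocyte, epithelial and pluripotency genes free RNA from other cells was not excluded, as the whole day 16 libraries of 2i and serum had Sfn at 32.81 and 230.4 CPM, Krt19 at 11.93 and 646.4 CPM and Dppa5a at 9205 and 2414 CPM. The 2 media filled this class from different clusters, and the class of serum day 16 (301 cells) came mostly from a cluster led by Isg15, Ifit3 and Ifit1.

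**Figure D4:**
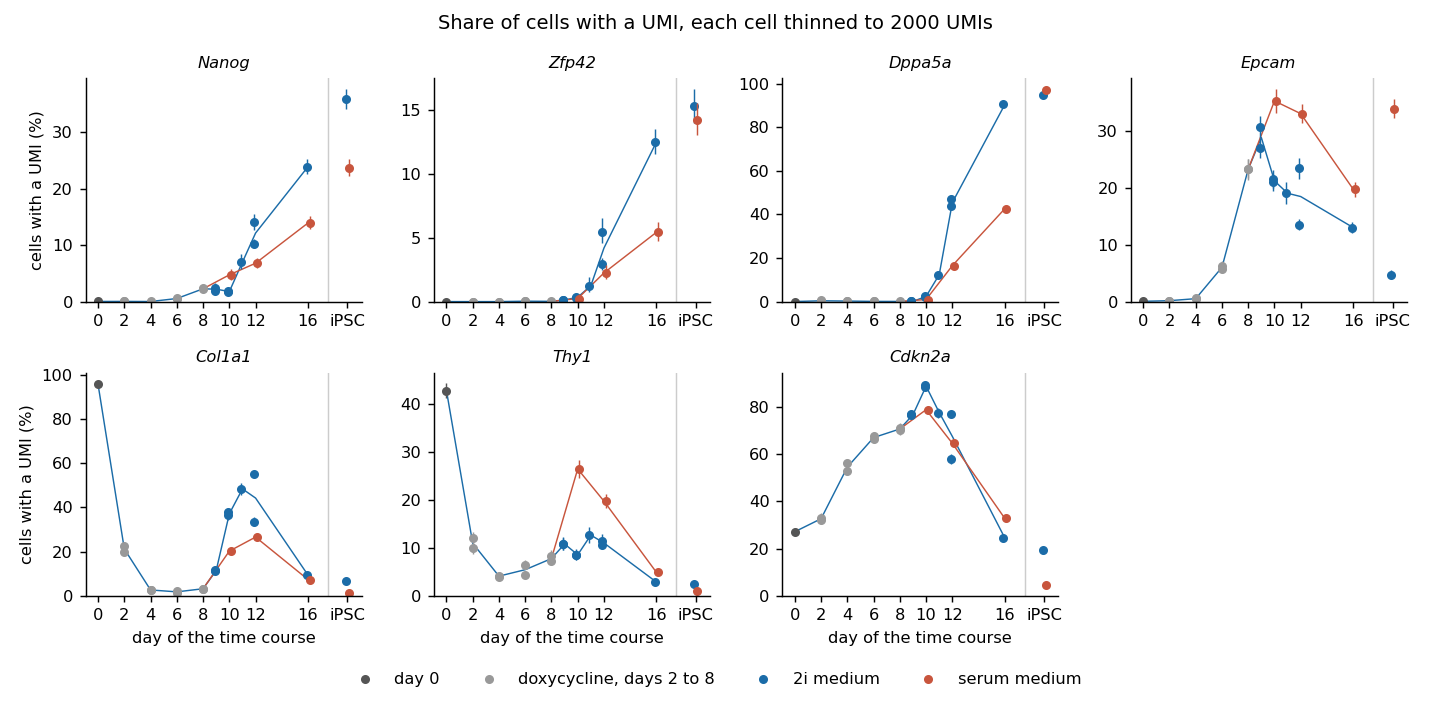
Share of cells with at least 1 UMI of 7 genes in each library, after each cell was thinned to 2000 UMIs. Error bars are exact 95% binomial intervals.

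Counted by cell at 2000 UMIs each, Col1a1 was seen in 95.62% of cells on day 0, 19.64% and 22.65% in the day 2 replicates and 2.785% and 2.401% on day 4. It was seen again in 54.97% and 33.41% on 2i day 12, where pluripotent-like cells had it in 12.4% and 4.66%. Dppa5a was seen in 0.02515% of cells on day 0, 90.45% [89.55 to 91.29] on 2i day 16 and 42.64% on serum day 16. The fibroblast-like cells of those day 16 libraries, as a background, had it in 32.64% and 13.15%; among cells with at least 2000 UMIs the median depth was 7903 UMIs overall and 4519 in that background for 2i, and 5269 and 4876 for serum, and the unthinned shares were 94.29% and 52.09%. Nanog was seen in 2.387% and 2.151% of cells in the day 8 replicates, 23.94% on 2i day 16 (1.71% in the background) and 35.91% in the 2i iPSC line (7.17%; median depth 12782.5 and 7154 UMIs). Zfp42 reached 15.29% in that line (3.14% in the background). Epcam went from 0.0503% on day 0 to 23.21% and 23.32% on day 8 and 35.25% on serum day 10 (2.47% in the background). Cdkn2a was in 27.11% of cells on day 0, 89.16% and 88.43% on 2i day 10 (31.4% and 31.8% in pluripotent-like cells) and 4.437% in the serum iPSC line. Thy1, a fibroblast surface gene, was in 42.73% on day 0 and 26.39% on serum day 10. No background was measured for Thy1 in these 2 libraries or for Col1a1 on days 0, 2 and 4. The same holds for Cdkn2a on day 0 and for Nanog and Epcam on day 8. There the background class held fewer than 50 cells, so low shares cannot be told from free RNA.

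The main genes lie at these places in GRCm38: Col1a1 (ENSMUSG00000001506, chr11 94936224 to 94953042), Lox (ENSMUSG00000024529, chr18 52516067 to 52529867), Isg15 (ENSMUSG00000035692, chr4 156199424 to 156200818), Neurog2 (ENSMUSG00000027967, chr3 127633135 to 127635631), Epcam (ENSMUSG00000045394, chr17 87635979 to 87651129), Nanog (ENSMUSG00000012396, chr6 122707489 to 122714633) and Dppa5a (ENSMUSG00000060461, chr9 78367052 to 78368177). The others are Notum (ENSMUSG00000042988, chr11 120653788 to 120661175), Dusp6 (ENSMUSG00000019960, chr10 99263231 to 99267489), Saa3 (ENSMUSG00000040026, chr7 46711998 to 46715700), Krt17 (ENSMUSG00000035557, chr11 100256217 to 100261029), H19 (ENSMUSG00000000031, chr7 142575529 to 142578143) and Cdkn2a (ENSMUSG00000044303, chr4 89274471 to 89294653).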

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

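All tests of the patterns in this part were written before their results were seen, except the tests of interferon UMIs by cell (1.952%) and of the immune list on day 0 (2.17 CPM), which were chosen only after the result was seen. A test of the difference itself flagged the medium effect, which differed between day 10 and day 16 for 5722 genes and 13 gene lists, of which 1 was called with an estimated correlation.

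Interferon response genes were higher in the day 0 library than on day 2. The list took 650.3 CPM on day 0 against 82.5 and 88.9 CPM in the day 2 replicates. Immune cells in the day 0 library as the source are argued against: the immune list took 2.17 CPM there and 3.884 and 4.968 CPM on day 2, with 0 UMIs of Ptprc, Cd52 and Tyrobp on day 0. Only 1.952% of the interferon UMIs lay in cells with a UMI of the immune list. The share of cells with an interferon UMI at 2000 UMIs per cell, 47.46% (15.28% and 16.35% on day 2), lay between the 2 bounds written for it, and with no background share measured it decided nothing. Scaling is argued against too, since the list's median log2 change with library size alone was -7.936. A property of the single library could not be separated from one of the day, as there was 1 day 0 library, so these cannot be told apart, and an interferon response of these fibroblasts in culture stays open and untested.

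The 2i day 12 replicates differed more than other pairs did. The median absolute log2 ratio was 0.222, against a median of 0.1091 over the other pairs, although the day 2 pair came close at 0.2133. After weighting both libraries to the same cluster shares the ratio was 0.163, so 47.73% of the excess was kept, just under the bound of 50% written for this test. That is consistent with different shares of the cell classes as part of the cause (fibroblast-like 65.91% and 41.44%). Thinning each cell to the same number of UMIs left a ratio of 0.2284, with 0.2149 as the highest of the other pairs. Equal UMIs per cell thus did not remove the difference. Thinning also raised the ratio of the other pairs, on day 8 from 0.08163 to 0.1239, because it adds counting noise. A fall was therefore unlikely beforehand, and depth is not excluded.

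The medium difference was not the same on day 16 as on day 10. Over 2144 of the 5722 genes, those with at least 20 CPM in fibroblast-like cells, the median absolute log2 difference in these cells was 0.3216 on day 16 and 0.3072 and 0.3032 on day 10, a ratio of 1.047. The sums were thinned to 1725127 UMIs each, and the part of these values due to counting noise was not measured. The ratio therefore does not show whether the size of the difference changed in these cells. Different cell classes in the media as the cause cannot be told apart from a change within cells, because different clusters hold the fibroblast-like class in the 2 media. Free RNA of trophoblast-like cells in the day 16 serum library also stays open: 14.82% of the genes lower in 2i, 469 of 3164, were at least 4-fold higher in trophoblast-like cells. A slower course in serum was not tested, and no biological explanation was tested for this pattern.

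Of 56 possible splits of the 8 libraries, 54 were estimable and 40 were run. Only 1 of the 40 called as many genes between the media as the real split, which is the real split itself, and 5004 genes was the highest among the others. Within fibroblast-like cells it was also 1 of 40, with 318 as the highest of the others. Besides the real split, only the exchange of the day 16 labels kept the media of each day apart, and it called 5004 and 222 genes. The rest mixed the media of some day under 1 label, which raises the spread. The rank of the real split therefore decides nothing.

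Shares in the groups that no comparison used lay above the interval of day 0 for the values below. Among cells thinned to 2000 UMIs, Nanog was seen in 0.5457% on day 6 and 6.998% on 2i day 11, Zfp42 in 1.243% and Dppa5a in 12.36% on 2i day 11. Epcam was seen in 0.5154% on day 4, 6.021% on day 6 and 19.03% on 2i day 11, and Cdkn2a in 54.49%, 67.02% and 77.63%. On 2i day 11 fibroblast-like cells, as a background, had Nanog in 0.7802%, Zfp42 in 0%, Dppa5a in 2.861% and Epcam in 1.3%, and pluripotent-like cells had Cdkn2a in 33.63%. No background was measured on days 4 and 6, so the low shares of those days cannot be told from free RNA.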

How the results depend on the processing

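Of the named-gene results under the alternatives, 9245 were the same, 568 lost their call, 10 gained one and 32 had the other sign, counting 1 with a log2 change of 0. Counts of called genes were within 1.5-fold of the main count in 95 cases and beyond it in 18. Single lists stayed the same in 134 cases and lost their call in 91. Class shares per library were within their interval or spread in 746 cases and moved in 178, and class differences between the media kept their sign in 40 cases and lost it in 2. The alternative with the cells named in the normalized matrix was not run. Cells with more than 1000 genes, and variable genes without those called between the media, were chosen after the data were seen. The cause of these moves was not tested unless stated.

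A minimum fold of 2 left, by construction, 3815 genes for day 2 against day 0, 4781 for day 8 against day 2, 1915 for serum day 10, 1804 for 2i day 9, 3830 for 2i day 12, 1715 between the media and 2587 for iPSC lines against day 16. Leaving out 1 replicate gave 2181 to 2193 genes for serum day 10, 2476 to 2816 for 2i day 9 and 1582 to 3979 between the media within fibroblast-like cells. A fit of the 2 groups alone gave 7060 genes for 2i day 9, the additive fit of 8 libraries gave 265 between the media and kept 27 of 101 named genes, and 2i alone gave 3018 for iPSC lines against day 16. With a block for the replicate number the counts were 8560 for day 8 against day 2, 4535 for 2i day 9 and 7375 for 2i day 12.

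With an estimated correlation the called lists went from 10 to 1 for day 2 against day 0, 5 to 0 for day 8 against day 2, 14 to 0 for serum day 10, 8 to 0 for 2i day 9, 7 to 0 for 2i day 12, 14 to 1 between the media, 13 to 1 for day 16 against day 10, 13 to 0 for iPSC lines and 10 to 0 within fibroblast-like cells.

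The gap between the highest and lowest library in cells with a UMI, at 2000, 1000 and all UMIs, was 35.91, 19.62 and 80.59 points for Nanog, 15.29, 8.471 and 59.19 for Zfp42, 96.96, 94.11 and 98.89 for Dppa5a, 35.2, 24.12 and 72.89 for Epcam, 94.42, 85.55 and 96.21 for Col1a1, 41.86, 26.44 and 63.05 for Thy1 and 84.72, 70.96 and 80.42 for Cdkn2a.

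The share of fibroblast-like cells, 8.661 points higher in 2i, was -2.545 at resolution 2 and -1.638 without the 2% of cells with the most UMIs. Shares per library moved by up to 27.8 points for fibroblast-like (50 components), 60.4 for epithelial-like, 31.3 for keratinocyte-like and 9.69 for trophoblast-like (resolution 0.5) and 12.5 for pluripotent-like cells (resolution 2).

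With 1000 cells per library the log2 change of Tnnt3 for day 2 was 0.00, so it had no sign. These log2 changes had the other sign. With 1000 cells per library: Lyz2 (2.28) for day 2, Klf4 for serum day 10 (-0.023) and 2i day 9 (-0.11), Pou5f1 for 2i day 12 (0.056) and Postn for iPSC lines (0.13). With library size scaling: Pou5f1 for day 8 (-0.29). For 2i day 9, leaving out 1 replicate gave -0.24 to 0.68 for Sox2 and -0.057 to 0.10 for Klf4, with the other sign without day 8 replicate 2 or 2i day 9 replicate 1. For 2i day 12 it gave -0.86 to 0.19 for Pou5f1. Between the media without day 10: Lefty2 (0.84), Cldn5 (0.42), Rnf43 (-0.15) and Sp5 (-0.56); without day 12: Dnmt3b (0.36) and Pou5f1 (-0.18); without day 16: Krt15 (1.59), Slc2a1 (0.24) and Pou5f1 (-0.13). For iPSC lines in 2i alone: Tdgf1 (-0.027), Zeb2 (0.10), Plac1 (0.14), Kdr (0.12), Mmp13 (1.44), Spry4 (-0.59), Axin2 (0.72), Ldha (-0.031) and Myc (0.40), and the smallest was that of Lss, iPSCs vs D16 (-0.00255). In serum alone it was Dusp4 (1.04).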

Other observations

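The courses below were chosen only after the values were seen, and beyond the comparisons reported above they were not tested. Cdkn2a, the Ink4a/Arf locus that limits reprogramming, stood at 192.1 CPM on day 0, 399.4 (SD 29.8) on day 4, 581.1 (SD 10.3) on day 6 and 648 (SD 12.7) on day 8. It was highest on 2i day 10 (SD 12.4 between replicates), was 1148 CPM on 2i day 11, and ended at 202.8 CPM on 2i day 16 and 426.1 CPM on serum day 16, with 146.5 and 31.52 CPM in the 2i and serum iPSC lines. Xist, the RNA of the inactive X chromosome, went from 438.9 CPM on day 0 to 103.4 CPM on 2i day 16, 64.56 CPM in the 2i line and 14.45 CPM in the serum line, while serum day 16 kept 420.9 CPM.

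Nanog reached 3.167 CPM on day 6, 72.65 CPM on 2i day 11, 109.6 CPM (SD 18.7) on 2i day 12 and 168.4 CPM on 2i day 16, and 108 CPM on serum day 16. The cluster of serum day 16 led by the germline genes Stra8 and Dazl, with the placental genes Prl7d1, Ctsj and Prl4a1 among its 10 top genes, held 1181 cells, 99.32% of them from that library. In that library Prl7d1 and Ctsj were at 286.7 and 310.4 CPM over all cells that were not trophoblast-like. Free RNA may thus account for these placental genes. H19 stood at 1851 CPM on serum day 12 and 14.8 CPM in the 2i line, and Cdkn1c at 1597 CPM on serum day 12.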
